A study of Arabidopsis thaliana with 4 samples.

How the data were processed

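PARE-seq (parallel analysis of RNA ends, also called degradome sequencing) was run on mixed-stage inflorescences of Arabidopsis thaliana plants grown in long days. The method sequences the 5′ ends of uncapped RNA. An RNA cut under the guidance of a microRNA (miRNA) leaves a tag that starts opposite nucleotide 10 of the miRNA. There were 4 libraries, 1 each from wild-type Col-0, ddm1-2, rdr6-15 and the double mutant ddm1-2 rdr6-15. Per the labels, RNA was extracted with Tri reagent and sequenced on an Illumina HiSeq.

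Each deposited file lists distinct tags of 18 to 20 nt with a count, the number of reads of that exact sequence. The values were whole numbers from 1 up and were not normalised. TAIR 10 is the genome build in the submitters' processing notes. The trimming tool, its filters and the aligner are not given in the sources used here. No molecular identifiers were used, so counts include PCR copies.

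Tags were matched to the nuclear, mitochondrial and plastid genomes of the RefSeq assembly TAIR10.1 by exact match on both strands, without mismatches. A tag with several matches was split evenly over them. Tags that matched an organelle genome were set aside, and the remaining nuclear reads were the denominator to which the tags of each library were scaled (CPM). A gene's tags were those whose 5′ end lay inside the gene on its own strand. The reference has no track of transposon fragments. The class of transposon genes was therefore taken as the nuclear pseudogenes marked as partial in the annotation, plus the Sadhu elements, 3902 genes in all. It holds 8 of 8 known transposon genes of a fixed list, and a few of its members may be other pseudogenes. The remaining 33997 nuclear genes were treated as other genes. Superfamilies were assigned by translated search (tblastx, e-value 1e-10) to 19 seed genes, which were chosen after the data were seen. Athila elements had their own seed gene and were kept as a group apart from the other Gypsy elements.

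The comparisons were ddm1-2 with Col-0, ddm1-2 rdr6-15 with rdr6-15, rdr6-15 with Col-0, and ddm1-2 rdr6-15 with ddm1-2. With 1 library per genotype there is no replicate error within a genotype, and no p-values were computed. A fit of the main effects of both mutations, whose 1 residual degree of freedom is their interaction, was not run. A gene was counted as higher or lower by a size rule. The rule asked for a CPM ratio of 4 or more, an exact conditional Poisson 95% interval of the ratio that excludes 2, and at least 20 tags in the higher library. Intervals of shares are 95% Wilson intervals. A library with under 1 tag of a gene after splitting was set to a floor of 3 counts, and such a ratio is given as a lower bound. Intervals and floors cover counting error only.

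The named genes were chosen by rule. For each comparison and direction, and apart for transposon genes and other genes, the rule took the 10 with the largest ratio. They had to have at least 100 tags in the higher library, meet the size rule, and differ at least 2 times in the same direction in the other background. Where a library of the other background had under 1 read, that ratio rested on the floor of 3 counts. Meeting the condition then does not show agreement between backgrounds, as for several genes lower in ddm1-2 rdr6-15 than in ddm1-2. DDM1 and RDR6, list members with the highest share or ratio or a value unlike the rest of their list, and the 10 transposon sites with most tags were added. These rules, the size rule, the gene lists, the site penalties and 22 alternatives were fixed before the data were examined. Another 13 alternatives were added after the data were seen.

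The 15 gene lists were miRNA targets, TAS transcripts, tasiRNA targets, small RNA machinery, DNA methylation and chromatin, genes silenced by DNA methylation, RNA decay, floral organ identity, pollen, tapetum, photosynthesis, meristem and cell division, heat and stress, housekeeping, and known transposon genes. For each, the median log2 ratio was set against 10000 random lists of the same size, matched on mean abundance within 100 ranks either side.

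For each known target, the best ungapped site of its miRNA was found with a penalty of 1 per mismatch and 0.5 per G:U pair, multiplied by 2 at nucleotides 2 to 13. A penalty of up to 5 was allowed. The reads that start opposite nucleotide 10 were counted as a share of all sense tags of the gene, with positions offset by 2 to 10 nt as background. Shares were pooled over sites and also given as a median per site, with an order-statistic 95% interval. Genes needed a mean of 20 tags over the 4 libraries. In transposon transcripts, sites of 76 small RNAs (74 of them miRNAs) with a penalty of up to 4 were searched in 3912 transcripts covering 9067 kb. A site was counted when it had at least 5 tags that were also the highest within 20 nt either side. The backgrounds were the offset positions and 20 shuffles of each small RNA.

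The counting was tested on simulated data with changes planted in 50 genes per fold. At a planted fold of 8, the size rule recovered 37 of the 50 genes in the ddm1-2 against Col-0 design and 49 in the rdr6-15 against Col-0 design. At a planted fold of 4 it recovered 20 and 23. It called 0 unchanged genes and 0 genes in the wrong direction, and 380 of 380 planted cleavage sites were found. The simulated counts were Poisson draws without PCR copies, split tags or biological spread, and the planted sites were perfect matches. These results check that the steps run as written and give no error rates for the real libraries.

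The alternatives were TMM factors and median-of-ratios size factors, other minimum counts, only tags with 1 genome match, each distinct tag counted once, thinning to the smallest library (2172989 reads), other denominators and strands, other site penalties and positions, and all 350 annotated mature miRNA sequences. TMM moved the median of all genes by 0.22 on the log2 scale for ddm1-2 against Col-0 and by -0.17 for ddm1-2 rdr6-15 against ddm1-2. The tools were Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, numba 0.67.0, matplotlib 3.10.9 and BLAST+ 2.17.0. Tags without an exact match were left out. No small RNA reads were among the files, so production of small RNAs was not measured.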

Results

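The libraries hold 5′ ends of uncapped RNA from inflorescences, mostly unopened buds, of 4 genotypes with 1 library each. The labels give their purpose as checking predicted miRNA cleavage sites in transposons. DDM1 is a chromatin remodeller needed for DNA methylation of transposons, and RDR6 is an RNA-dependent RNA polymerase that makes precursors of small interfering RNAs, including trans-acting siRNAs (tasiRNAs). Depth differed between libraries, with 2172989 reads in Col-0, 26351880 in ddm1-2, 6412658 in rdr6-15 and 7947398 in ddm1-2 rdr6-15. An exact genome match was found for 92.9% of reads in Col-0, 93.0% in ddm1-2, 93.0% in rdr6-15 and 93.2% in the double mutant. After organelle tags were set aside, 1467949, 18489955, 3695010 and 5081039 reads remained, in the same order. Protein-coding genes held 87.4% of these in Col-0, 74.8% in ddm1-2, 80.4% in rdr6-15 and 76.0% in the double mutant. The most abundant tag took 9.72%, 6.71%, 15.1% and 8.60% of the reads. No genotype has replicates, so differences were not tested against biological spread, and intervals cover counting error only.

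DDM1 (AT5G66750, chromosome 5, 26648897 to 26653191) had 6 tags in Col-0, 119 in ddm1-2, 32 in rdr6-15 and 30 in the double mutant. These are 4.09, 6.44, 8.66 and 5.90 CPM (tags scaled to the nuclear reads of the library). RDR6 (AT3G49500, chromosome 3, 18348974 to 18353673) had 23, 418, 42 and 69 tags, or 15.7, 22.6, 11.4 and 13.6 CPM. Tag counts do not check the alleles, because the labels do not give the lesions.

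Decay tags of transposons were far more abundant in both libraries that carry ddm1-2. Their share of nuclear tags was 13.9-fold higher in ddm1-2 than in Col-0 (95% interval 13.5 to 14.4) and 9.47-fold higher in ddm1-2 rdr6-15 than in rdr6-15 (9.26 to 9.69). Among the transposon genes assigned to a superfamily, Athila retrotransposons, which lie mostly near centromeres, and CACTA DNA transposons had the largest increases in ddm1-2. SDC, an F-box gene silenced by methylation of repeats in its promoter, was also higher in both. The median of the pollen genes was lower in both, with 9 of 12 measured members at least 2 times lower and 2 higher in each. These comparisons ask what loss of DDM1 does to the pool of cleaved and decaying transcripts, with RDR6 present or absent, and they share no library.

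Sense tags of transposon genes made up 0.277% of nuclear tags in Col-0 (Wilson interval 0.268 to 0.285), 3.85% in ddm1-2 (3.84 to 3.86), 0.222% in rdr6-15 (0.217 to 0.227) and 2.1% in the double mutant (2.09 to 2.11). With only tags that match 1 genome place, the ratio of the double mutant to rdr6-15 was 6.31. At least 1 tag was seen for 709 transposon genes in Col-0, 2871 in ddm1-2, 1130 in rdr6-15 and 2142 in the double mutant, counts that also follow depth. The top 10 transposon genes held 29.2%, 21.7%, 31.4% and 23.4% of these tags.

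**Figure D1:**
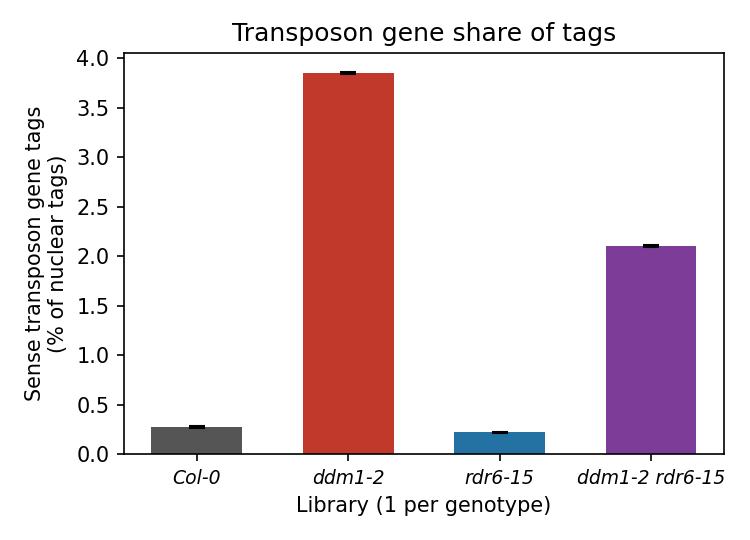
Sense tags of transposon genes as a percent of nuclear tags in each of the 4 libraries, with 95% Wilson intervals as error bars. The bars stand at 0.277% for Col-0, 3.85% for ddm1-2, 0.222% for rdr6-15 and 2.1% for ddm1-2 rdr6-15.

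By superfamily, a grouping made after the data were seen, the Athila share was 31.7-fold higher in ddm1-2 than in Col-0 (27.1 to 37.3) and 10.9-fold higher in the double mutant than in rdr6-15 (9.56 to 12.4). CACTA elements were 30.2-fold (27.3 to 33.4) and 48.4-fold higher (43.9 to 53.6). Gypsy elements, with Athila counted apart, were 14.4-fold and 7.14-fold higher, and Copia elements 5.99-fold and 3.91-fold higher. Mutator elements were 3.97-fold and 3.89-fold higher, and LINE elements 3.40-fold and 1.75-fold higher. Sadhu elements had ratios of 1.17 and 0.891. The 2239 transposon genes with no assigned superfamily were 19.0-fold and 14.2-fold higher. They held 2.05% of nuclear tags in ddm1-2, more than any assigned superfamily.

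By the size rule, 693 of the 1552 transposon genes with enough tags were higher in ddm1-2 than in Col-0, and 0 were lower. A lower call needed at least 20 tags in Col-0, which only 28 transposon genes had, and with no minimum 5 were lower. In ddm1-2 rdr6-15 against rdr6-15, 551 of 628 were higher and 0 lower, where only 50 had the 20 tags in rdr6-15 that a lower call needed. Among the 628 genes with enough tags in both comparisons, 451 and 551 were higher and 441 were higher in both, where independent lists would share 396. With only tags of 1 genome match, the counts of higher genes were 328 and 301. With all tags, the higher genes in ddm1-2 included 114 of 168 Athila genes, 100 of 166 CACTA genes and 39 of 124 Copia genes. In the double mutant, 93 of 94 CACTA genes and 38 of 41 Athila genes were higher than in rdr6-15. Such fractions depend on depth and on the minimum count, so they cannot be set against each other between the comparisons. With at least 100 tags in the higher library they were 693 of 912 and 186 of 203 over all transposon genes.

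**Figure D2:**
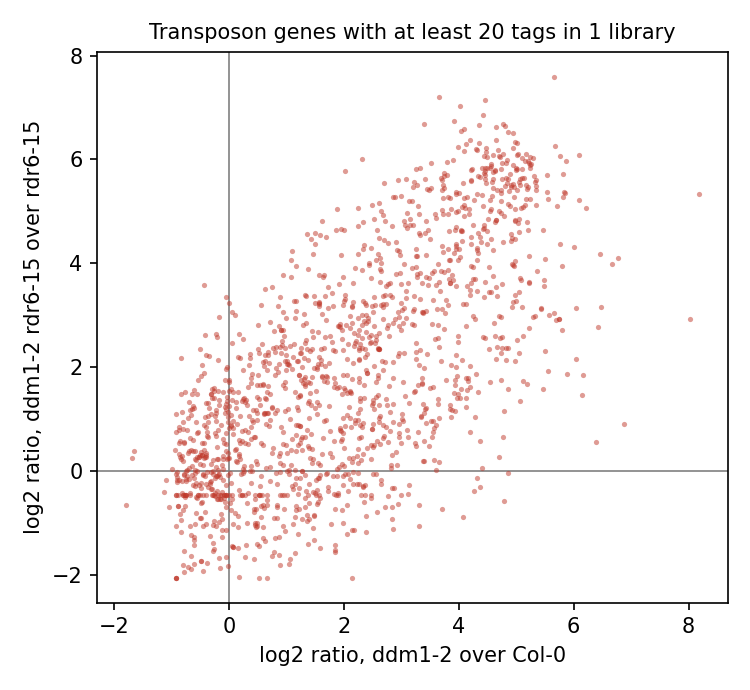
Log2 ratio of CPM for each transposon gene in ddm1-2 against Col-0 (horizontal axis) and in ddm1-2 rdr6-15 against rdr6-15 (vertical axis), with genes under 1 tag in a library placed at the floor of 3 counts. Of the 693 genes higher in ddm1-2 by the size rule, 587 were at least 2 times higher in the other background.

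AT3G42650 was 88.9-fold higher in ddm1-2 than in Col-0 (57.6 to 145), with 22529 reads against 20. AT4G08598 had 3649 reads against 1, a ratio of 290 (52.0 to 11447), and AT3G33118 had 3261 against 1, a ratio of 259 (46.4 to 10228). The Athila gene AT1G42050 was 87.4-fold higher (22.6 to 873), the Mutator gene AT3G30170 110-fold higher (19.7 to 4338) and the Copia gene AT4G11375 74.6-fold higher (20.6 to 617). In Col-0 they had 1.78, 1 and 2 reads. In the double mutant against rdr6-15, the CACTA gene AT5G28524 was 101-fold higher (46.0 to 275), with 830 reads against 6, or 86 against 0 with tags of 1 genome match. The LINE gene AT2G15550 had 266 reads against 1, a ratio of 193 (34.4 to 7669).

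Known transposon genes had a median log2 ratio of 3.13 over 5 of 8 measured members in ddm1-2 against Col-0, at percentile 100 of matched random lists, and of 3.22 in the double mutant against rdr6-15, or 1.66 there after thinning to the smallest library. By the size rule, 3 were higher in each. The Copia element EVD had 1.5 reads in Col-0, 332 in ddm1-2, 0.333 in rdr6-15 and 11 in the double mutant. CACTA1 had 1.87, 206, 0.667 and 152 reads, and ATMU1, a Mutator element, had 2, 274, 1 and 59. These reads are not scaled to the depth of the libraries.

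Among other genes, 143 were higher and 217 lower in ddm1-2 than in Col-0, of 19342 with enough tags. With TMM factors this split was 172 and 172, and with median-of-ratios factors 173 and 170. With at least 100 tags in the higher library it was 143 and 53, since a larger minimum leaves out more genes of the smaller Col-0 library. In the double mutant against rdr6-15, 134 were higher and 118 lower of 16260. Among 16235 genes with enough tags in both comparisons, 122 and 134 were higher and 202 and 109 lower. The comparisons shared 100 higher and 61 lower genes, where independent lists of those sizes would share 1.01 and 1.36. The class of other genes is not free of transposons, as AT2G06420 below shows, so the shared higher genes may include transposons. AT4G16215 was 82.8-fold higher in ddm1-2 than in Col-0 (31.1 to 328), and AT5G38190 was 43.0-fold higher (23 to 91.7). AT2G06420 was 110-fold higher in the double mutant than in rdr6-15 (53.1 to 278), but with tags of 1 genome match it had 13 reads against 2, a ratio of 4.94. It is annotated as an En/Spm-like transposon. The ratio of AT4G16215 also rests mostly on tags with several genome matches. Of its 3822 reads in ddm1-2, only 98 were from tags of 1 genome match, against 0 in Col-0. These counts are not scaled to depth, and such tags had 14104941 nuclear reads in ddm1-2 and 1274466 in Col-0. Tags of 1 genome match therefore do not show an 82.8-fold difference for this gene.

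Genes silenced by DNA methylation had a median log2 ratio of 3.97 in ddm1-2 against Col-0 (percentile 99.8) and of -1.39 in the double mutant against rdr6-15 (percentile 0.125), over 3 genes. After thinning to the smallest library, which leaves FWA out, the latter median was 1.43. SDC had 6 reads in Col-0, 1184 in ddm1-2, 3 in rdr6-15 and 174 in the double mutant. FWA, a homeobox gene silenced in most tissues, had 1.5, 323, 2.5 and 1. QQS, a regulator of starch content, had 2, 286, 61 and 32. Reads of these genes are not scaled to the depth of the libraries.

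Pollen genes had a median log2 ratio of -2.45 in ddm1-2 against Col-0 and of -1.63 in the double mutant against rdr6-15, below all matched random lists in each (percentile 0). After thinning to the smallest library the former was -1.68. Of 12 measured members, 9 were at least 2 times lower in each comparison and 7 in both, and by the size rule 3 were lower in each. VGD1, a pectin methylesterase of pollen tubes, was 8.19-fold lower in ddm1-2 (6.99 to 9.59), with 407 reads against 265 in the smaller Col-0 library. Outside the list, AGP6, an arabinogalactan protein of pollen, was 4.62-fold lower in the double mutant than in rdr6-15 (3.41 to 6.34). Tapetum genes, which feed developing pollen, had medians of -0.01 (percentile 60.7) and -0.60 (percentile 0.88).

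SAG12, a protease of senescent leaves, was 58.4-fold lower in ddm1-2 than in Col-0 (52.0 to 65.6) and 2.11-fold lower in the double mutant than in rdr6-15. Its reads were 1650 in Col-0, 356 in ddm1-2, 212 in rdr6-15 and 138 in the double mutant. PR5, a defence gene, was higher in ddm1-2 by the size rule, with a log2 ratio of 2.75.

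Precursors of tasiRNAs left more tags in both libraries that carry rdr6-15. TAS1C and TAS2, the precursors cut under miR173, were several-fold higher in rdr6-15 than in Col-0 and in ddm1-2 rdr6-15 than in ddm1-2. The pooled share of transposon tags was lower, in rdr6-15 at 0.802 times that in Col-0 (0.773 to 0.833) and in the double mutant at 0.546 times that in ddm1-2 (0.542 to 0.549). With only tags of 1 genome match these ratios were 0.943 and 0.525. Superfamilies differed in rdr6-15 against Col-0, from 0.396 for CACTA (0.343 to 0.456) to 1.01 for Copia (0.907 to 1.13) and 1.37 for LINE elements (1.19 to 1.58). In the double mutant the difference from ddm1-2 was largest for Athila elements and on chromosome 3. These comparisons ask what loss of RDR6 does, with DDM1 present or absent, and they share no library.

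TAS1C was 11.3-fold higher in rdr6-15 than in Col-0 (8.93 to 14.4) and 11.3-fold higher in the double mutant than in ddm1-2 (10.4 to 12.3). TAS2 was 4.26-fold (3.46 to 5.30) and 7.31-fold higher (6.69 to 8.0). With each distinct tag counted once, the ratios were 1.24 and 1.09 for TAS1C and 2.06 and 2.79 for TAS2. Most tags of both transcripts start at the miR173 cleavage position. Counting distinct tags once therefore cannot tell repeated cleavage from PCR copies. TAS3B was 5.40-fold higher in the double mutant than in ddm1-2 (4.03 to 7.26). The miRNA gene MIR3933 was 11.9-fold (4.98 to 37.1) and 19.3-fold higher (13.2 to 29.2). The median log2 ratio of TAS transcripts was 1.85 and 1.91 over 7 of 8 members (percentile 100 in each), the latter 1.5 after thinning, and 3 of them were higher by the size rule in each comparison. Without RDR6 as the variable, their medians were -0.30 in ddm1-2 against Col-0 (percentile 32.3) and -0.20 in the double mutant against rdr6-15 (percentile 14.1).

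Targets of tasiRNAs, among them auxin response factors, had medians of 0.20 (percentile 65.7) in rdr6-15 against Col-0 and 0.98 (percentile 100) in the double mutant against ddm1-2. By the size rule, 2 were higher in the double mutant than in ddm1-2, AT4G29770 with a log2 ratio of 3.20 and AT4G29760 with 2.75. The list's medians were -0.58 (percentile 8.29) in ddm1-2 against Col-0 and 0.49 (percentile 99.5) in the double mutant against rdr6-15.

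In rdr6-15 against Col-0, 2 of 50 transposon genes with enough tags were higher and 0 lower. They are SADHU3-2 (AT3G42658), with 113 reads against 1, and the Copia gene AT5G35935, with 113 against 6, and they are named here after their values were seen. A lower call needed at least 20 tags in Col-0, which only 28 transposon genes had. Among 15066 other genes, 24 were higher and 53 lower. Of those higher, 5 were also higher in the double mutant than in ddm1-2, where independent lists would share 0.04. Of those lower, 0 were also lower there, where independent lists would share 0.02. Only 7 of the 50 genes lower in the double mutant than in ddm1-2 had enough tags in both comparisons. An overlap of 0 therefore says little about agreement. The peroxidase gene AT5G64120 was 5.75-fold lower in rdr6-15 than in Col-0 (4.30 to 7.74).

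In the double mutant against ddm1-2, 401 of 1552 transposon genes were lower and 1 was higher, AT3G43730 with 179 reads against 162, named after its values were seen. A higher call needed at least 20 tags in the double mutant, which 628 transposon genes had. With only tags of 1 genome match, 205 were lower, and with TMM or median-of-ratios factors 0 were higher. With all tags, the lower genes included 103 of 168 Athila genes, 40 of 165 Gypsy genes and 32 of 166 CACTA genes. Tags shared between copies were split evenly over them, so a loss at some copies can appear at others. Among the named lower Athila genes, AT4G06704 had 270 reads in ddm1-2 and AT3G33072 had 644. With tags of 1 genome match they had 1 and 504, the lowest and highest of these genes. Superfamilies were not counted with such tags. The Athila share was 4.65-fold lower than in ddm1-2 (4.50 to 4.81), the Gypsy share 2.45-fold lower and the CACTA share 1.57-fold lower. AT5G32035 was 143-fold lower (45.7 to 801), with 2.64 reads against 1371, and AT1G36520 was 32.2-fold lower, or 0 reads against 32 with tags of 1 genome match. Among 19342 other genes, 28 were higher and 50 lower, or 20 and 64 with TMM factors and 21 and 63 with median-of-ratios factors. AT3G43310 was 10.3-fold lower, with 32.5 reads against 1221.

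The lower values of the double mutant were unevenly spread over the genome. Among transposon genes higher in ddm1-2, measured with tags of 1 genome match, the median log2 ratio of the double mutant to ddm1-2 was -3.23 for 72 genes on chromosome 3. For such genes on the other chromosomes it was -0.51. With all tags the medians were -2.74 and -0.85, and 67.9% and 31.3% of such genes were at least 4 times lower. The next values are again for tags of 1 genome match. On chromosome 3, 67 of the 72 genes were at least 4 times lower, or 93.1% (84.8 to 97.0), against 41 genes elsewhere, or 16%. The medians of chromosomes 1, 2, 4 and 5 were -0.42, -0.43, -0.93 and -0.41. Genes outside the transposon class that were higher in ddm1-2 showed the same split. Their medians were -3.02 for 20 genes on chromosome 3 and -0.60 for 110 genes elsewhere. Without chromosome 3, the transposon share of the double mutant was 0.632 times that of ddm1-2. The split by chromosome was made after the data were seen.

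**Figure D3:**
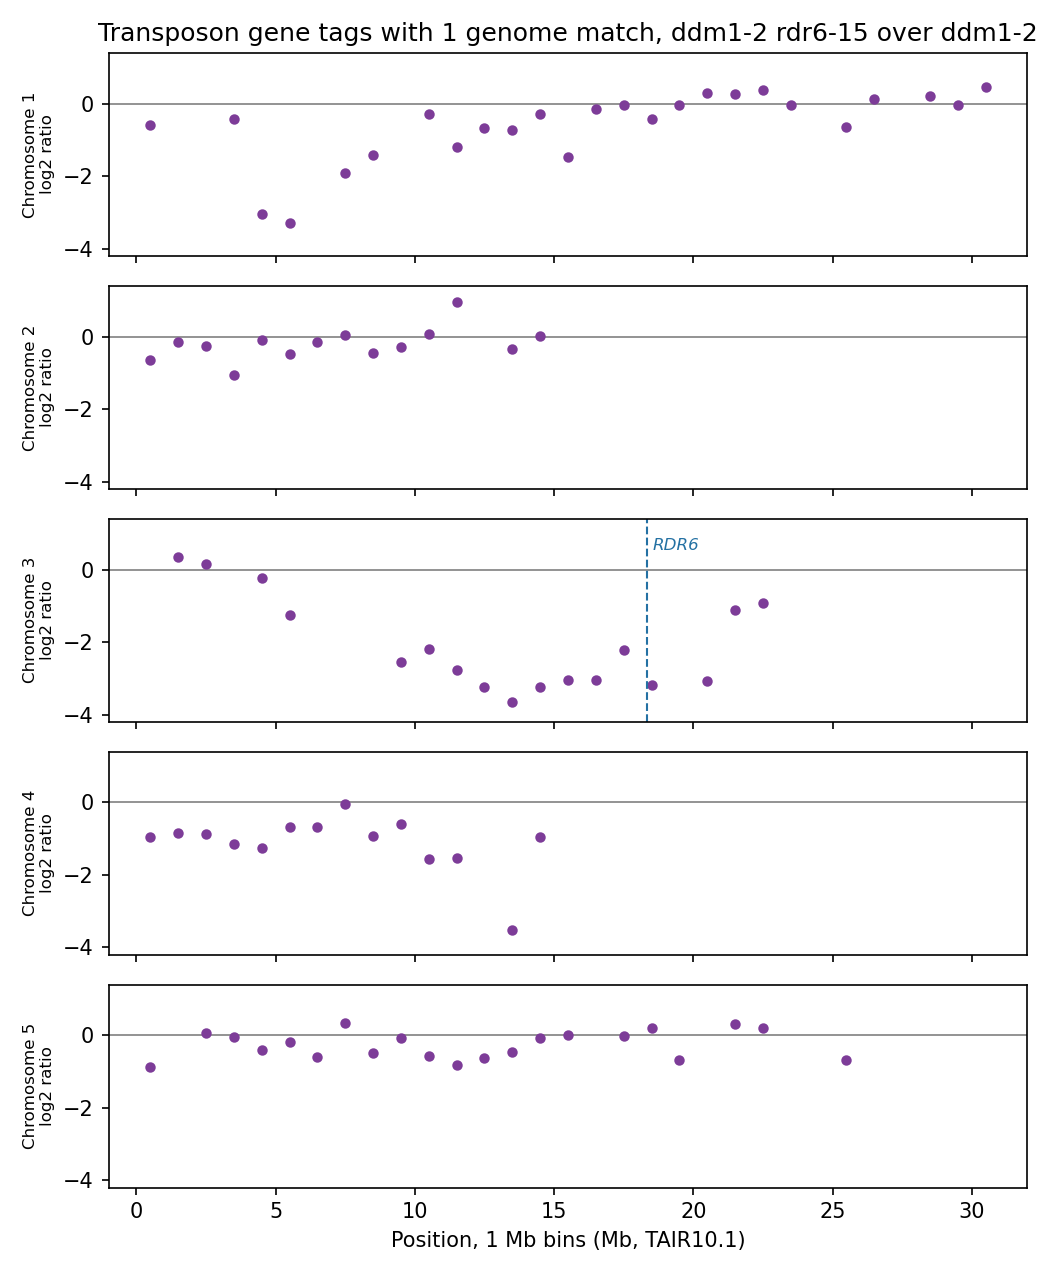
Log2 ratio of CPM in ddm1-2 rdr6-15 against ddm1-2 for transposon genes in bins of 1 Mb along each chromosome, with a dashed line at RDR6 on chromosome 3. The 11 measured bins from 9 to 21 Mb of chromosome 3 lie between -3.65 and -2.19.

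Many known targets of miRNAs carried cleavage tags, with at least 1 read at 46 of 72 sites in Col-0, 62 in ddm1-2, 58 in rdr6-15 and 59 in the double mutant. Such counts also follow depth, as the genes had 6769, 70584, 14041 and 19852 reads in the same order. HAM1, a GRAS regulator of meristems cut under miR171, and NAC1, a transcription factor cut under miR164, had most of their tags at the cleavage position. Over 72 sites with enough tags, the cleavage position held 27.5% of gene tags in Col-0 (26.5 to 28.6), 19.8% in ddm1-2 (19.5 to 20.1), 19.6% in rdr6-15 (19.0 to 20.3) and 21.1% in the double mutant (20.5 to 21.7). The mean at offset positions was 0.465%, 0.468%, 0.333% and 0.364%. The median per site was lower, at 7.88%, 6.35%, 7.53% and 10.3%, with wide intervals (1.79 to 17 in Col-0 and 3.98 to 16.4 in the double mutant). With only tags of 1 genome match the medians were 2.60%, 3.53%, 4.76% and 4.35%. Over the 42 sites with at least 100 gene tags they were 15.5%, 7.77%, 13.1% and 14.6%. HAM1 alone gave 945 of the 1864 site reads of Col-0.

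The cleavage tag was the most abundant of its gene at 35 sites in Col-0, 36 in ddm1-2, 38 in rdr6-15 and 38 in the double mutant. It exceeded every offset position at 43, 56, 54 and 54 sites, counts that also follow depth. HAM1 (AT2G45160) had 945, 6138, 1031 and 1813 cleavage reads, or 63.4%, 52.5%, 57.3% and 60.2% of its tags. NAC1 (AT1G56010) had 78.1%, 71.0%, 76.0% and 76.3%. ARF10, an auxin response factor cut under miR160, had 35.4%, 56.3%, 20.5% and 26.7%. AGO1, the miRNA effector, had 2.59%, 3.50%, 2.92% and 3.88%. PHO2, a target of miR399, had 0 reads at the cleavage position of its best site in every library, with 1013 gene reads in ddm1-2. Only the best site of each gene was counted, so cleavage of PHO2 at any other site would be missed.

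**Figure D4:**
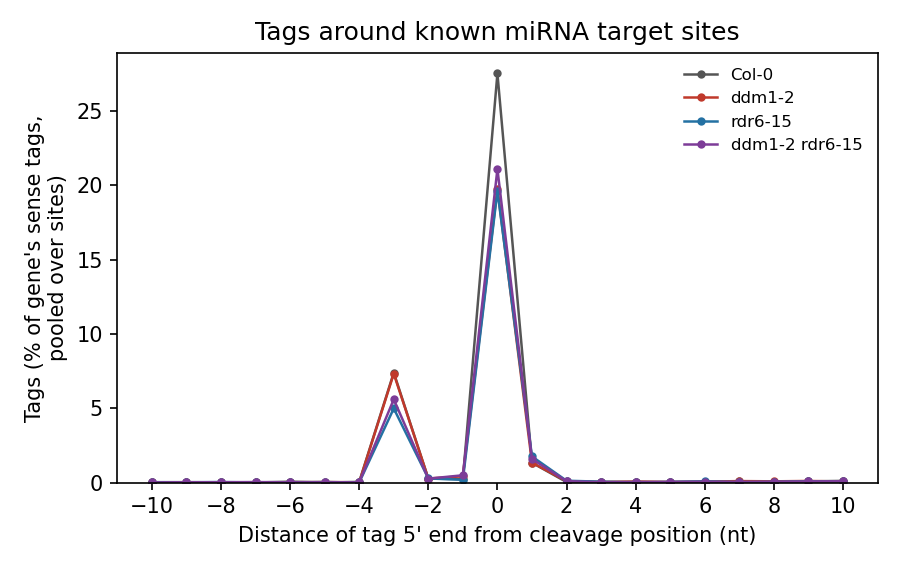
Pooled percent of gene tags at each position around the predicted cleavage position of 72 known miRNA sites, from 10 nt before to 10 nt after it, in each library. The peak at offset 0 is 27.5%, 19.8%, 19.6% and 21.1% in Col-0, ddm1-2, rdr6-15 and ddm1-2 rdr6-15, and the smaller peak at offset -3 in Col-0 is mostly HAM1, with 454 of 501 reads.

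At the cleavage positions of TAS transcripts, tags were far more abundant in the libraries with rdr6-15, while tags at tasiRNA target sites were few. The miR173 site of TAS1C had 51 reads in Col-0, 557 in ddm1-2, 2013 in rdr6-15 and 2254 in the double mutant. These were 69.6%, 74.2%, 96.8% and 96.5% of TAS1C tags. The miR173 site of TAS2 had 66, 541, 870 and 1307 reads, or 67.8%, 73.0%, 83.3% and 87.8%. The miR390 site of TAS3C had 2, 15, 26 and 25 reads. TAS3A had 0 reads at its best ungapped site in every library, of 242, 3533, 1047 and 1629, and so lowered the pooled share of TAS transcripts most in Col-0 and ddm1-2. The median share per TAS transcript was 61.8%, 72.8%, 69.4% and 84.4%.

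Over the tasiRNA targets, the cleavage position held 7 of 1276 reads in Col-0 (0.549%), 79 of 9806 in ddm1-2 (0.806%), 4 of 2350 in rdr6-15 (0.170%) and 0 of 3295 in the double mutant, which allows up to 0.116%. ARF2, an auxin response factor cut by TAS3-derived tasiRNAs, had 6, 65, 1 and 0 cleavage reads. ARF4 had 0, 6, 1 and 0. ARF3 had 1, 1, 0 and 0. Reads of each gene were counted at its best site only.

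**Figure D5:**
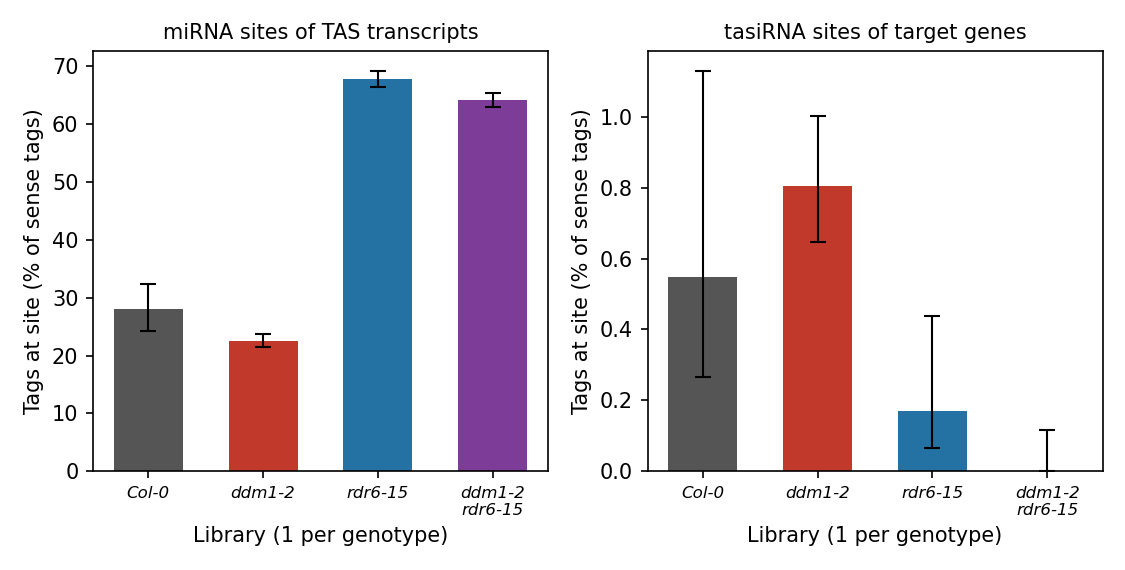
Percent of gene tags at the predicted cleavage position in each library, pooled over TAS transcripts in one panel and over tasiRNA targets in the other, with 95% Wilson intervals. The TAS values, which the 0 reads at the TAS3A site lower, are 28.1%, 22.6%, 67.7% and 64.2% and the target values 0.549%, 0.806%, 0.170% and 0% in Col-0, ddm1-2, rdr6-15 and ddm1-2 rdr6-15.

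Predicted miRNA sites in transposon transcripts, the stated subject of the libraries, had few tags at the cleavage position. Of 34 predicted sites with a penalty of up to 4, 0 met the rule of at least 5 tags and the local maximum in each of the 4 libraries. Shuffled small RNAs gave on average 12.7 sites, with a mean of 0 in Col-0 and 0.05 in each other library that met the rule. With a penalty of up to 5 there were 134 sites, of which 0, 1, 0 and 0 met the rule, against a mean of 0.278, 0.444, 0.222 and 0.278 at offset positions and of 0.05, 0.2, 0.1 and 0.1 for shuffled small RNAs. With at least 2 tags as well, 0, 3, 1 and 2 sites met it, against at most 1, 2, 1 and 1 in any shuffle, a setting chosen after the data were seen. At a penalty of up to 4 and at least 5 tags, cleavage by the small RNAs of the fixed list was not detectable at this depth in annotated transposon transcripts. With all 350 annotated mature miRNAs, 1, 3, 1 and 1 sites met that rule, against offset means of 1.78, 3.17, 2.39 and 2.56.

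The site with most tags in the search with the fixed list was a miR159a site with a penalty of 4.5, at position 13741133 on the minus strand of chromosome 3, shared by AT3G33076, AT3G33084 and AT5G28335. With miR159c, which is not in the fixed list, its penalty was 3. It had 0, 87, 1 and 3 reads at the cleavage position in Col-0, ddm1-2, rdr6-15 and the double mutant, of 0, 93, 1 and 3 reads in the 41 nt around it. The site reads AGGATCTCCCTTCATTCCAAA, and miR159 otherwise cuts MYB transcripts such as MYB33. A miR838 site in AT3G42727 had 3, 5, 0 and 2 reads, and a miR396b site in AT1G60120 had 0, 0, 2 and 2, and the tags of both also match a gene that is not a transposon gene. A miR159a site in AT4G22415 had 4 reads, and a miR156a site in AT1G16660 and a miR164a site in AT1G53810 had 3 each, all in ddm1-2. The remaining 4 of the 10 sites with most tags, in AT2G04990, AT5G35057, AT3G33076 and AT1G23930, had 1 read each in 1 library, and the tag in AT2G04990 also matches a gene outside the transposon class.

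Other gene lists, in the order ddm1-2 against Col-0, rdr6-15 against Col-0, the double mutant against ddm1-2 and the double mutant against rdr6-15, had these medians. Targets of miRNAs had -0.20, -0.04, 0.19 and -0.06 (percentiles 46.2, 48.0, 92.3 and 54.4). Small RNA machinery had -0.06, 0.06, 0.43 and 0.11 (66.4, 53.9, 99.3 and 98.5). DNA methylation and chromatin genes had -0.07, 0.05, 0.11 and 0.01 (72.0, 54.3, 34.9 and 80.1). Genes of RNA decay had -0.18, 0.06, 0.40 and 0.09 (49.7, 58.1, 91.6 and 92.0). Floral organ identity genes had -0.26, 0.47, 0.57 and -0.21 (41.1, 97.3, 99.8 and 9.73). Photosynthesis genes had 0.27, 0.57, -0.03 and -0.08 (79.9, 99.8, 75 and 16.4). Meristem and cell division genes had 0.25, 0.04, -0.26 and -0.17 (95.9, 67.0, 10.7 and 32.4). Heat and stress genes had -0.33, -0.72, -0.05 and 0.13 (29.7, 0.85, 26.9 and 96.7), and housekeeping genes had 0.02, 0.14, 0.02 and -0.04 (59.2, 84.2, 56.6 and 47.6). The next medians are for rdr6-15 against Col-0 and the double mutant against ddm1-2. They were -0.59 and -1.30 for genes silenced by DNA methylation (percentiles 8.2 and 0.245) and -0.53 and 0.03 for pollen (7.4 and 37.9). They were 0.63 and 0.12 for tapetum (98.7 and 51.0), and -0.65 and -0.35 for known transposon genes (10.2 and 9.29).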

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

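All tests in this part were chosen only after the result was seen.

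Several tag classes outside the comparisons were above their Col-0 level in some libraries. Tags antisense to transposon genes made up 0.276% of nuclear tags in ddm1-2 and 0.154% in ddm1-2 rdr6-15, against 0.0401% in Col-0 (Wilson interval 0.0370 to 0.0435). Tags outside annotated genes made up 10.9% in ddm1-2, 8.35% in rdr6-15 and 8.79% in ddm1-2 rdr6-15, against 3.79% in Col-0. Tags that match an organelle genome made up 35.4% in rdr6-15 and 29.3% in ddm1-2 rdr6-15, against 25.3% in Col-0 and 22.8% in ddm1-2.

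AT4G35690, a gene of unknown function on chromosome 4, went opposite ways in the backgrounds of each mutation. Its log2 ratio was -4.04 in ddm1-2 against Col-0 and 3.18 in the double mutant against rdr6-15. It was -4.83 in rdr6-15 against Col-0 and 2.39 in the double mutant against ddm1-2. Its reads were 51 in Col-0, 39 in ddm1-2, 4.5 in rdr6-15 and 56 in the double mutant, and the difference was not tested.

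Pollen genes had few tags in both libraries that carry ddm1-2. With TMM factors the median log2 ratio in ddm1-2 against Col-0 was -2.24, below the limit set for scaling as the cause. Such factors move all genes and all random lists by the same amount, so this was no independent test of scaling. With every library thinned to the smallest the median was -1.68, below the limit set for depth as the cause. Of 12 measured genes, 7 were at least 2 times lower in both comparisons. Fewer flowers with pollen in the tissue taken and an effect of ddm1-2 on pollen cannot be told apart, because each genotype has 1 library and the tissue was of mixed stages.

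Tags at a miR159 site in AT3G33084 appeared in ddm1-2, where a search from tag peaks gave 3 sites with a penalty of up to 4, of which 1, a miR159c site, lay in a transposon gene and the others antisense in the genes of their own miRNAs. Shuffled small RNAs gave a mean of 0.2 over all peaks and 0.05 over peaks in transposon genes, and at the site's own penalty of 3 a mean of 0.05 and 0. With 1 site and 20 shuffles, a chance match of an abundant tag to a small RNA is left open. Of the tags at the site, 0 also matched a gene outside the transposon class, but the tag is shared by AT3G33076, AT3G33084 and AT5G28335 and cannot be assigned among them. Cleavage of these transcripts under miR159 is a hypothesis that the data leave open.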

How the results depend on the processing

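The alternatives for the transposon share without chromosome 3, the wider and peak-led site searches, and the gene lists and named genes were chosen after seeing the data. Each genotype has 1 library. A fit of the main effects of both mutations over the 4 libraries, which leaves 1 residual degree of freedom if the mutations are taken to act independently, was not run. For the main results, 220 values under an alternative kept their direction and stayed within their interval or within 1.5 times the count, 89 moved and 1 reversed. Counts of 0 under both settings were taken as unchanged. For the remaining values, which include the named genes, these numbers were 445, 52 and 0. For named genes, 326 of 371 values stayed within their interval, 45 moved and 0 reversed, and another 70 gave no value because they were bounds, against a library at 0, that do not exclude the main interval. The cause was not tested unless stated; thinning, distinct tags and tags of 1 genome match leave fewer counts by construction.

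Transposon share ratios are given for ddm1-2/Col-0, rdr6-15/Col-0, double/ddm1-2 and double/rdr6-15. They were 11.3, 0.943, 0.525 and 6.31 with tags of 1 genome match, and 15.5, 0.873, 0.55 and 9.78 over protein-coding plus transposon tags. Without chromosome 3 they were 13, 0.771, 0.632 and 10.6, or 9.94, 0.900, 0.672 and 7.42 with tags of 1 genome match as well. With both strands they were 13, 0.837 and 8.51 (not double/ddm1-2, which stayed). With distinct tags they were 9.94, 0.587 and 7.22 (not rdr6-15/Col-0, which stayed).

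Transposon genes higher in ddm1-2/Col-0 were 328 with tags of 1 genome match and 375 with distinct tags, and 5 were lower with no minimum. In double/rdr6-15, 186 were higher with at least 100 tags, 301 with tags of 1 genome match, 195 with distinct tags and 242 after thinning. In double/ddm1-2, 205, 97 and 183 were lower with tags of 1 genome match, distinct tags and thinning. The number higher there was 0 with TMM, 0 with median-of-ratios factors, 9 with no minimum, 2 with tags of 1 genome match and 0 with distinct tags. Other genes in ddm1-2/Col-0 were 82 higher with distinct tags, and 53, 473 and 112 lower with at least 100 tags, no minimum and distinct tags. In rdr6-15/Col-0, 10, 7 and 14 were higher with at least 100 tags, distinct tags and thinning, and 12, 80 and 26 lower with at least 100 tags, no minimum and distinct tags. In double/ddm1-2, 8, 58 and 6 were higher with at least 100 tags, no minimum and distinct tags, and 11 and 22 lower with distinct tags and thinning. In double/rdr6-15, 46, 47 and 58 were higher and 27, 29 and 52 lower with at least 100 tags, distinct tags and thinning.

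Known sites held 29.1%, 21.6%, 21.6% and 23.2% of gene tags within 1 nt of the position (Col-0, ddm1-2, rdr6-15, double), and 26.4%, 19.3%, 18.4% and 19.6% with tags of 1 genome match. With at least 100 gene tags they held 28.7% in Col-0, 20.4% in ddm1-2 and 21.9% in the double mutant, and 24 sites in rdr6-15 and 25 in the double mutant were the most abundant of their gene, from fewer sites tested. Transposon sites that met the rule were 1 in ddm1-2 at a penalty of up to 5, and 1 in rdr6-15 and 1 in the double mutant with at least 2 tags, where shuffles gave at most 1 in each. With all annotated mature miRNAs there were 1, 3, 1 and 1, and 1, 4, 1 and 1 at a penalty of up to 5, below the means at offset positions (1.78, 3.17, 2.39 and 2.56, and 2.5, 4.94, 3.17 and 3.5). With a penalty of up to 5 and at least 2 tags there were 3, 1 and 2 in ddm1-2, rdr6-15 and the double mutant, against offset means of 0.722, 0.222 and 0.389 and at most 2, 1 and 1 in any shuffle. From tag peaks, at a penalty of up to 4, there was 1 in ddm1-2, in a transposon gene, and 0 in the other libraries. At a penalty of up to 5 there were 2 in transposon genes in ddm1-2, against a mean of 0.2 and at most 2 for shuffled small RNAs.

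After thinning, list medians were 1.5 for TAS transcripts in double/ddm1-2, -1.68 for pollen in ddm1-2/Col-0 and 1.66 for known transposon genes in double/rdr6-15. For genes silenced by DNA methylation in double/rdr6-15 the median reversed from -1.39 to 1.43, where FWA drops out for lack of tags. Of list medians outside the random range, 53 of 54 values kept their direction. The Col-0 library, the smallest, limits what can be measured against it.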

Other observations

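All tests in this part were chosen only after the result was seen.

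As with SAG12, some other genes had their highest scaled tag count in Col-0. DIN2 (AT3G60140), a glucosidase induced in the dark and in senescence, had log2 ratios of -4.41 in ddm1-2 and -5.40 in rdr6-15 against Col-0. DOX1 (AT3G01420), a fatty acid dioxygenase of defence, had -4.44 and -3.59. Both were chosen after their values were seen and stand for no wider group: the defence gene PR5 (AT1G75040) had its lowest count in Col-0, with 5 reads. With 1 Col-0 library no explanation was tested.

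SADHU3-2 (AT3G42658) had 1 read in Col-0, 261 in ddm1-2, 113 in rdr6-15 and 126 in the double mutant. These reads are not scaled. The ddm1-2 library had 18489955 nuclear reads and the rdr6-15 library 3695010, so the scaled count was higher in rdr6-15 than in ddm1-2. QQS (AT3G30720) was higher in rdr6-15 than in Col-0 as well, with a log2 ratio of 3.6.

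Transposon genes of chromosome 3 that were higher in ddm1-2 had few tags in the double mutant. Tags shared between transposon copies are argued against, since the median log2 ratio was -3.23 with tags of 1 genome match and -2.74 with all tags. A loss of RDR6 acting alike on every chromosome is argued against, since the median elsewhere was -0.51. A candidate explanation is that silent transposons were inherited with the segment around RDR6, for which the bins at least 4 times lower would form a long run that holds RDR6. That run held 11 measured bins, from 9 to 21 Mb of chromosome 3, and the longest run elsewhere held 2. It may not be the whole cause, since these genes were still above rdr6-15, with a median log2 ratio of 1.60 on chromosome 3 against 4.49 elsewhere.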
